A study of Mus musculus with 12 samples.

How the data were processed

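RNA from immortalised striatal cells of homozygous Hdh knock-in mice was measured on 12 Illumina mouse expression BeadChip arrays. The lines carry 7 CAG repeats (Hdh7/7) or 109 CAG repeats (Hdh109/109) in the huntingtin gene. Each line was left untransfected, transfected with an empty vector, or transfected with a construct labelled DNRest, which gives 6 groups of 2 arrays. Per the labels' protocols, total RNA was DNase-treated, amplified and labelled with biotin. The series design text calls the samples biological replicates, but nothing in the labels says whether paired RNAs came from separate cultures, so p-values measure the spread between these arrays, which may be technical in part. There is 1 line per genotype, so genotype cannot be told apart from other differences between the lines.

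The group of each array was taken from its title, which matches its genotype characteristic and transfection characteristic. For 6 of the 12 arrays the source name gives the other genotype. The title was kept, and the source name was used once as an alternative. A treatment field that describes the cells as untreated was not used, because titles and characteristics give the transfection.

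The deposited unnormalized table holds the bead signal of 44505 probes per array as a linear intensity, with a detection p-value for each probe and array, per the file headers. The detection p-values lie on steps of 1 in 1610. The scanner software is not given in the sources used here, and limma is named in the submitters' processing notes without a version or a role. The deposited series matrix holds log2 values of the same arrays. Its columns share their quantiles, with medians of 3.061 to 3.073, and have a floor at log2 of 0.1. How the authors corrected the background of the log2 values is not given in the sources used here.

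The rows of the series matrix did not match their probe identifiers. By identifier, the rank correlation with the unnormalized signal was 0.017 to 0.034 over the 12 arrays. The line difference of bright probe pairs of one gene correlated at r = 0.72 over 1662 genes in the unnormalized table and at r = 0.0037 over 1072 genes in the series matrix. The series matrix therefore served only for counts over unnamed rows, taking as many of the brightest rows as there were probes tested. Its named genes, gene lists and overlaps were not used.

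Signals were processed with limma 3.58.1 in R 4.3.3. Background was corrected with nec, which took the background mean and spread of each array from the detection p-values, with an offset of 16. Arrays were then quantile normalized (neqc). Probes with a detection p under 0.01 on at least 2 of the 12 arrays were tested, which kept 15224 probes. A linear model with 1 mean per group was fitted to all 12 arrays, with 6 residual degrees of freedom and moderated variances (eBayes). Tests were two-sided, with Benjamini-Hochberg adjustment over all probes tested in a comparison, and a probe was called at an adjusted p under 0.05. Standard errors and adjusted p-values of single genes come from this limma fit.

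Gene names came from the platform annotation given with the values. Of the 44505 probes, 28471 had 1 gene symbol, 10 had several and 16024 were unnamed. Symbols were looked up by Entrez identifier in a RefSeq gene table of the GRCm38.p6 assembly, and 0 probes changed symbol. No genome build is used by the array files, so no coordinates are given. Each gene was represented by its probe with the highest mean log2 level, which gave 8487 genes tested.

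Where a probe was undetected on every array of the dimmer group, the change is given as at least N-fold. The bright group's mean log2 level was then set against the mean, over the dim arrays, of the higher of the lowest signal detected on that array and the probe's own signal. No such fold is given where it falls under 1 or where both groups are undetected.

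There were 18 gene lists with 412 entries, written down with the comparisons, the tests and the rule for named genes before the data were examined. Lists with at least 2 genes tested, 16 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera asks whether a list's genes moved more than other genes, and fry whether they moved one way on balance. Adjustment was over the lists within a comparison. Named genes were Htt and Rest, up to 10 genes with the highest and 10 with the lowest log2 fold change per comparison, and up to 4 members of each list. The first kind had to be called, with arrays that did not overlap, or with the same sign in every state for an average. Clone, predicted and unnamed symbols were left out. Genes or probes named outside this rule are marked as chosen after their values were seen.

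The 7 planned comparisons were genotype without transfection, genotype averaged over the transfection states, DNRest against empty vector in each line and averaged, the difference between the lines in that response, and empty vector against no transfection averaged over the lines. The overlap of genotype and DNRest genes was tested with Fisher's exact test, two-sided. The empty vector response in each line and the difference between the lines were added after the averaged result was seen.

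The alternatives were no background correction, median scaling, the series matrix, no detection filter, detection on all 12 arrays, the replicate number as a block, a trended and robust variance, the compared groups alone, a 2-fold minimum, each transfection state alone, the source name as genotype, the mean over a gene's probes, an estimated correlation for lists, and each array left out in turn. A pair of arrays with high background, and that pair with Hdh109/109 empty vector replicate 2, were also left out, both chosen after the data were seen. Slide as a block was not run because the files give no slide.

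Estimated background was 64.49 to 93.42 signal units on 10 arrays, 149.7 on Hdh7/7 empty vector replicate 2 and 142.1 on Hdh109/109 untransfected replicate 2. The number of arrays limits the precision of every comparison. The fit was tested on simulated data for the DNRest comparison in Hdh109/109 over 15224 probes, with the measured spread of each probe. Of 50 probes changed per size, it recovered 12% at a log2 change of 0.5, 56% at 1, 96% at 2 and 100% at 3, and it called 10 unchanged probes among 142 calls. Without any change it called 0. A simulated list of 20 genes shifted by 0.5 gave a camera p of 4.83e-21, and an unshifted list gave 0.347. The simulated noise was independent between genes and alike on all arrays. It therefore does not show how the tests behave with correlated list genes or noisier arrays. Plots were drawn with matplotlib.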

Results

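Gene expression was profiled in immortalised striatal cells from mice with 7 or 109 CAG repeats in the huntingtin gene, a cell model of Huntington's disease. The 12 arrays fall into 6 groups of 2, Hdh7/7 and Hdh109/109 cells each untransfected, with empty vector or with DNRest. In the study this construct is a dominant-negative form of REST, the repressor of neuronal genes in cells outside the nervous system; the labels give only its name. An array detected 10295 to 14370 of the 44505 probes. Arrays of 1 group correlated at r = 0.979 to 0.993 across probes, and arrays of different lines at r = 0.887 to 0.916.

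The probe for Htt, the gene that carries the repeat, was lower in Hdh109/109 cells. Its log2 level was 6.86 ± 0.25 (SD, n = 2) in untransfected Hdh7/7 cells and 5.11 ± 0.1 in Hdh109/109 cells, where it was undetected on all 6 arrays. The untransfected difference was at least 1.85-fold (limma, adjusted p = 6.53e-05). The signal lies near background, and the probe does not read the repeat length. The probe for Rest was undetected on all 12 arrays, with group means of 4.6 to 4.76 log2, and was not tested. It therefore gives no measure of the construct. By source name, 18 pairs of arrays of the same title genotype belong to different genotypes, and these correlated at r = 0.959 to 0.992, in the range of 1 line. All directions below follow the titles.

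The first comparison asked which genes differ between the untransfected lines. The largest differences were between genes that were bright in one line and undetected in the other. Gjb2, a gap junction connexin, was at least 66-fold higher in Hdh109/109 cells (log2 11.91 ± 0.11 against 4.87 ± 0.27, SD, n = 2; adjusted p = 7.15e-09). Zic1, a transcription factor of neural development, was at least 62.8-fold higher, and Gask1b, Slc38a4, an amino acid transporter, Bag3, a co-chaperone, and Sim2, a transcription factor, at least 61.6-fold, 43.3-fold, 36.8-fold and 35.8-fold. Thbd, Dnm3os and Rnase4, also named for their log2 fold change, were at least 20.7-fold, 16.9-fold and 15.4-fold higher. Dlk1, an imprinted gene, was detected in both lines and was 37.4-fold higher in Hdh109/109 cells (log2 fold change 5.22 ± 0.15, SE). In the other direction Prelp, a matrix proteoglycan, was at least 71-fold lower (adjusted p = 3.96e-09). The adhesion gene Cadm1, the engulfment receptor Megf10 and the vitamin D receptor Vdr were at least 36.9-fold, 28.2-fold and 27.5-fold lower. Sox2 and Fam167a, with Id4 and Epb41l4a, were at least 26.5-fold, 26.4-fold, 24.3-fold and 22.6-fold lower, and Atp6v0e2 and Sall3 at least 14-fold and 13.3-fold. In all, 2680 probes were higher and 2742 lower in Hdh109/109 cells, 35.6% of the 15224 tested, or 1536 and 1773 of 8487 genes. With median scaling in place of quantile normalization the count was 3242, and with a 2-fold minimum it was 2148.

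Markers of neural progenitors were lower in untransfected Hdh109/109 cells. Of 9 genes tested, 6 fell and 1 rose, with a median log2 fold change of -2.18, or -1.27 with undetected probes held at their bound. Sox2 and Pax6, transcription factors of neural stem cells, were at least 26.5-fold and 14.2-fold lower, and Hes1 and Id1, detected in both lines, were 5.87-fold and 7.78-fold lower. Adjusted over the list alone, 6 fell and 1 rose. Camera gave an adjusted p of 0.00345, and adjusted p = 0.0848 with an estimated correlation. Targets of p53 were also lower, with 9 of 15 genes down, 2 up and a median of -0.72. They included the cell cycle inhibitor Cdkn1a (log2 fold change -2.5 ± 0.17), Ccng1 (-1.67 ± 0.14), the p53 ligase Mdm2 (-1.59 ± 0.16) and Trp53inp1 (-1.48 ± 0.18). Camera gave an adjusted p of 0.015, and adjusted p = 0.202 with an estimated correlation.

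Non-coding and imprinted RNAs and endoplasmic reticulum stress genes were higher in Hdh109/109 cells. Of 9 non-coding or imprinted genes tested 7 rose, with a median of 1.48, or 0.85 with undetected probes at their bound. The imprinted growth factor Igf2 was at least 7.15-fold higher, the host gene Snhg1 at least 1.81-fold and the long non-coding RNA Pvt1 2.9-fold. The list includes the protein-coding genes Dlk1 and Igf2. Of 18 endoplasmic reticulum stress genes 10 rose and 0 fell, with a median of 0.53. The stress transcription factors Atf4 (1.51 ± 0.16) and Ddit3 (1.49 ± 0.21) and the pseudokinase Trib3 (1.14 ± 0.14) were among them, and Atf3 was at least 1.28-fold higher. Camera gave adjusted p-values of 0.00181 and 0.0127, and adjusted p = 0.0848 and adjusted p = 0.202 with an estimated correlation. With median scaling the stress list gave an adjusted p of 0.0523.

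Mesenchymal and matrix genes went both ways. Of 24 tested, 12 rose and 6 fell, with camera at an adjusted p of 0.0611 and fry at 0.000158. The collagen gene Col1a2 was at least 15.1-fold higher, the growth factor receptor Pdgfra at least 29.7-fold, Dcn at least 5.58-fold and Col3a1 9.93-fold. Of 9 striatal neuron markers tested, 4 rose and 3 fell, with Dlx2 and Penk at least 5.83-fold and 2.89-fold higher, Pde1b at least 10.1-fold lower and Meis2 4.04-fold lower. Astrocyte markers rose in 4 of 4 genes tested, with a median of 0.76. They were Glul (0.92 ± 0.28), Slc1a3 (0.75 ± 0.25), Gja1 (0.4 ± 0.13) and Apoe, at least 1.03-fold. Camera did not pass for either list (adjusted p = 0.831 and 0.0853), but fry, which does not compare with other genes, did (adjusted p = 0.00119 and 0.00309). The striatal list had a mean of 0.03, and the direction of its fry result was not kept. That result is therefore not read as a rise or a fall. Cholesterol synthesis genes fell in 9 and rose in 3 of 18 tested, with a median of -0.59. Camera gave an adjusted p of 0.176 and fry 0.000955. Hsd17b7 (-1.04 ± 0.12), Ebp (-0.95 ± 0.17) and Nsdhl (-0.86 ± 0.12) were lower, and Idi1 (1.34 ± 0.17) was higher.

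REST target genes did not move one way between the untransfected lines. Of the 62 genes listed, 12 were tested, 2 of them higher and 4 lower, with a median of -0.01 and a camera adjusted p of 0.831. Stmn2, a neuronal microtubule gene, was 25.7-fold higher in Hdh109/109 cells (log2 fold change 4.69 ± 0.15, SE). Bex1 was at least 3.6-fold lower, Vamp2 2.05-fold and Cdk5r1 1.77-fold lower. Adjusted over the list alone, 2 were higher and 4 lower. The list's mean was 0.07, so the sign of its centre depends on the measure. With undetected probes at their bound the median was 0.11. A probe undetected in both lines then shows only the offset between the arrays' lowest detected signals. These were log2 5.82 and 5.91 in untransfected Hdh7/7 cells and 5.75 and 6.2 in untransfected Hdh109/109 cells. The median of 0.11 is therefore no measure of these genes. Of 20 genes of REST and its corepressors tested 2 rose and 1 fell, with Rcor2 at 1.27 ± 0.15, Cdyl at -0.63 ± 0.14 and Sp1 at 0.45 ± 0.15, and a camera adjusted p of 0.458.

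**Figure D1:**
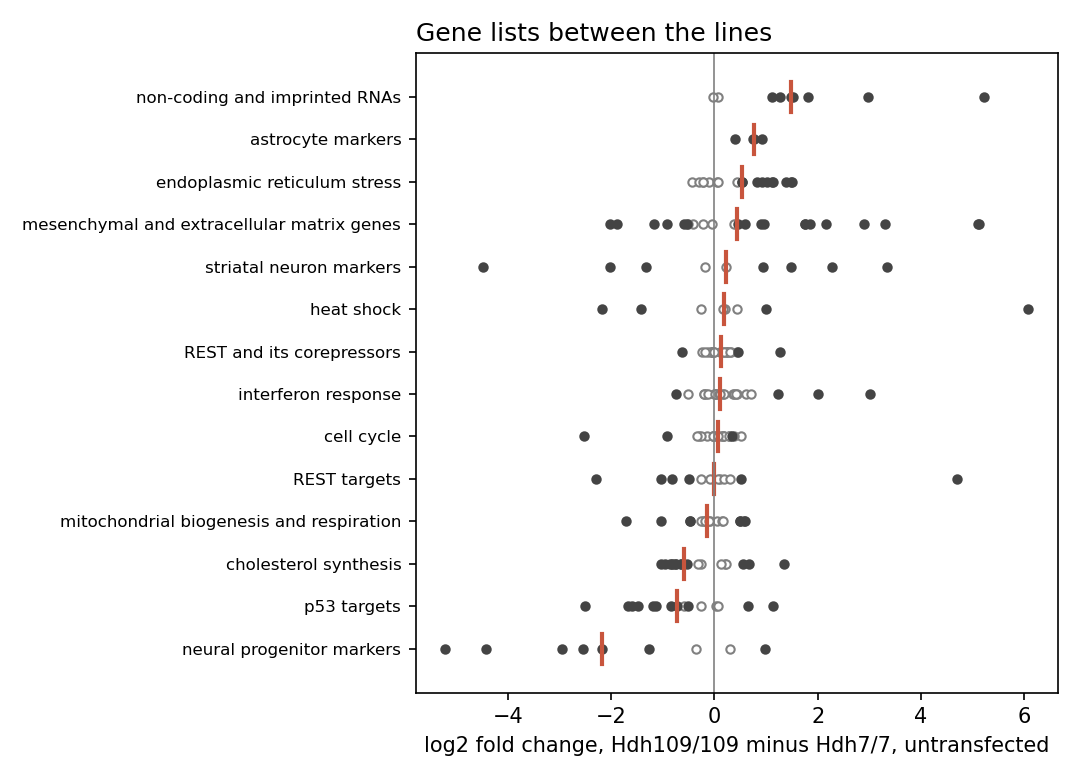
Log2 fold change between untransfected Hdh109/109 and Hdh7/7 cells (horizontal axis) for each gene tested in 14 gene lists (rows). Filled points are called genes, open points are not called, and red bars are list medians, from -2.18 for neural progenitor markers to 1.48 for non-coding and imprinted RNAs.

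The other lists showed no shift past the camera threshold in untransfected cells. Heat shock genes held 2 higher and 2 lower of 8, with Bag3 higher and Hspb8 (-2.17 ± 0.12) and Cryab (-1.42 ± 0.18) lower (adjusted p = 0.831). Cell cycle genes held 1 higher and 2 lower of 21, with Ccnd1 at -2.53 ± 0.14 (adjusted p = 0.862). Mitochondrial genes held 4 higher and 4 lower of 19, with Ppargc1a, a regulator of mitochondrial biogenesis, at least 2.62-fold lower (adjusted p = 0.831). Interferon response genes held 3 higher and 1 lower of 23, with Ccl5 and Cxcl10 at least 3.99-fold and 2.47-fold higher (adjusted p = 0.238). Of 2 endothelial markers tested Flt1 was lower (-1.29 ± 0.12, with adjusted p = 0.458 for the list), and neither of 2 oligodendrocyte markers was called (adjusted p = 0.831). Of the lists in this paragraph, fry passed for cell cycle genes (adjusted p = 0.00634) and endothelial markers (0.00096) and for no other. No microglia marker of 9 with a probe, and no Y-linked gene of 6, was detected on enough arrays to be tested.

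Averaged over the transfection states, 6 arrays against 6, 4487 probes were higher and 4298 lower in Hdh109/109 cells, 57.7% of those tested. Zic1, Gjb2 and Gask1b were at least 51.8-fold, 49.1-fold and 49.8-fold higher, and Pdgfra and Trim25 at least 39.3-fold and 19.5-fold. Cavin2, detected in both lines, was 40.7-fold higher. Cadm1, Epb41l4a, Sox2 and Megf10 were at least 32-fold, 23.5-fold, 23.4-fold and 22.4-fold lower, and Sox11 at least 14.4-fold. Of 3309 genes called without transfection, 1715 were called in the same direction in all 3 states, 868 higher and 847 lower, and 142 were called in the opposite direction in at least 1 state. Mesenchymal and matrix genes rose in 16 and fell in 5 of 24 (median 0.76; camera adjusted p = 0.00266, and adjusted p = 0.272 with an estimated correlation). Interferon response genes rose in 22 of 23, with a median of 2.03 (adjusted p = 1.33e-11, and adjusted p = 0.0741 with an estimated correlation). This average came from the transfected arrays. The median between the lines was 0.1 without transfection, with 3 genes higher and 1 lower, 3.53 with the empty vector and 2.83 with DNRest. Neural progenitor markers fell in 7 of 9 and p53 targets in 12 of 15, with medians of -1.6 and -0.76 (adjusted p = 0.0741 and adjusted p = 0.0808 with an estimated correlation). Endoplasmic reticulum stress genes rose in 12 of 18 and non-coding and imprinted RNAs in 7 of 9, with medians of 0.5 and 1.42, or 0.48 and 0.51 with undetected probes at their bound (adjusted p = 0.118 and adjusted p = 0.0741 with an estimated correlation). With the source name as genotype, 0 probes were called (limma, with 325 at an unadjusted p under 0.05). The source name did not vary within the untransfected arrays or within the DNRest arrays. Its term therefore compared only empty vector replicate 2 with replicate 1 in each line. This count does not show which genotype label is right.

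The next comparison asked what DNRest changes relative to the empty vector. Of 8487 genes, 8 were called higher in both lines. Lrp11 rose 10.2-fold in Hdh7/7 cells and 10.6-fold in Hdh109/109 cells (log2 fold change 3.35 ± 0.12 and 3.41 ± 0.12, SE, n = 2 against 2; adjusted p = 1.29e-06 and 1.09e-06). Unc13a, a synaptic vesicle priming gene, rose at least 2.41-fold and 3.41-fold, and the synapsin gene Syn1 at least 2.14-fold and 2.63-fold. The small GTPase gene Diras1 (2.29 ± 0.19 in Hdh109/109 cells), the neurite gene Gprin1 (at least 2.78-fold and 1.44-fold), Ttc9b, Gnptg and the phosphatase gene Ppm1e were the others. This overlap of 10 and 15 genes had an expectation of 0.0177 (Fisher's exact test, p = 4.35e-22). The 2 comparisons shared no array, but both took each probe's variance from the same fit. The calls are therefore not independent, and neither are the genes, so this p-value is descriptive only. Stmn2 (at least 1.09-fold) and Rtn2, which was undetected in both groups, were called in Hdh7/7 cells. Celsr3 (at least 2.22-fold), Smpd3 (2.15 ± 0.17), the channel gene Hcn2 (1.36 ± 0.19) and Cdk5r1 (1.08 ± 0.15) were called in Hdh109/109 cells, as were Slc5a5, Slc17a6 and Spire2, named after their values were seen. Adgrg2 was the 1 gene that fell, at least 1.32-fold in Hdh109/109 cells. The fitted changes of all 18 genes had the same sign in both lines.

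In probes, 15 rose and 0 fell with DNRest in Hdh7/7 cells, 20 rose and 1 fell in Hdh109/109 cells, and 20 rose and 1 fell in the average of both lines. Single arrays moved these counts. Without Hdh7/7 empty vector replicate 1, which left the replicate with high background as the only control, 1129 probes were called in Hdh7/7 cells and 205 in the average. Without either DNRest replicate of that line the Hdh7/7 count was 7. In Hdh109/109 cells it was 268 without empty vector replicate 1 and 11 without DNRest replicate 1. With median scaling, where the median of all probes shifted by -0.31, 15 probes rose and 102 fell in Hdh109/109 cells, and without background correction 20 rose and 13 fell. With the arrays of the compared groups alone, 0 probes were called in Hdh7/7 cells (limma, with 643 at an unadjusted p under 0.05) and 13 in Hdh109/109 cells. Replicates of the Hdh7/7 empty vector group differed most, with an SD of 0.343 log2 over probes against 0.176 to 0.249 in the other groups. The spread shared by all groups understates the noise of that group.

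Of the 12 REST targets tested, 3 rose with DNRest in Hdh7/7 cells and 4 in Hdh109/109 cells, and 0 fell. Adjusted over the list alone, 4 and 6 rose. The medians were 0.19 and 0.44, or 0.08 and 0.44 with undetected probes at their bound. Bounded medians also carry the offset between the arrays' lowest detected signals. In Hdh7/7 cells these signals were log2 5.99 and 6.73 with the empty vector and 6.07 and 6.06 with DNRest. In Hdh109/109 cells they were 5.87 and 5.65 with the empty vector and 6.07 and 5.88 with DNRest. The bounded medians therefore do not compare the lines. Camera gave adjusted p-values of 6.22e-07 and 3.5e-08, and adjusted p = 0.0186 and adjusted p = 0.0118 with an estimated correlation. The called members were Unc13a and Syn1 in both lines, Stmn2 in Hdh7/7 cells, and Celsr3 and Cdk5r1 in Hdh109/109 cells. A filter for detection on all 12 arrays removes genes that were undetected with the empty vector, Unc13a, Syn1 and Celsr3 among them, so the adjusted p-values of the remaining members (0.859 and 0.112) do not bear on these genes. The main filter also counts the DNRest arrays, so a gene undetected with the empty vector can enter the list through its rise. This selection favours a rise in the list tests. Without a detection filter the Hdh7/7 list was no longer called (camera adjusted p = 0.76). Interferon response genes had a median of -0.49 with DNRest in Hdh109/109 cells relative to the empty vector, with 0 of 23 called (camera adjusted p = 0.000236, and adjusted p = 0.522 with an estimated correlation). This median was -0.26 without Hdh109/109 empty vector replicate 2 and -0.28 without Hdh109/109 DNRest replicate 1.

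**Figure D2:**
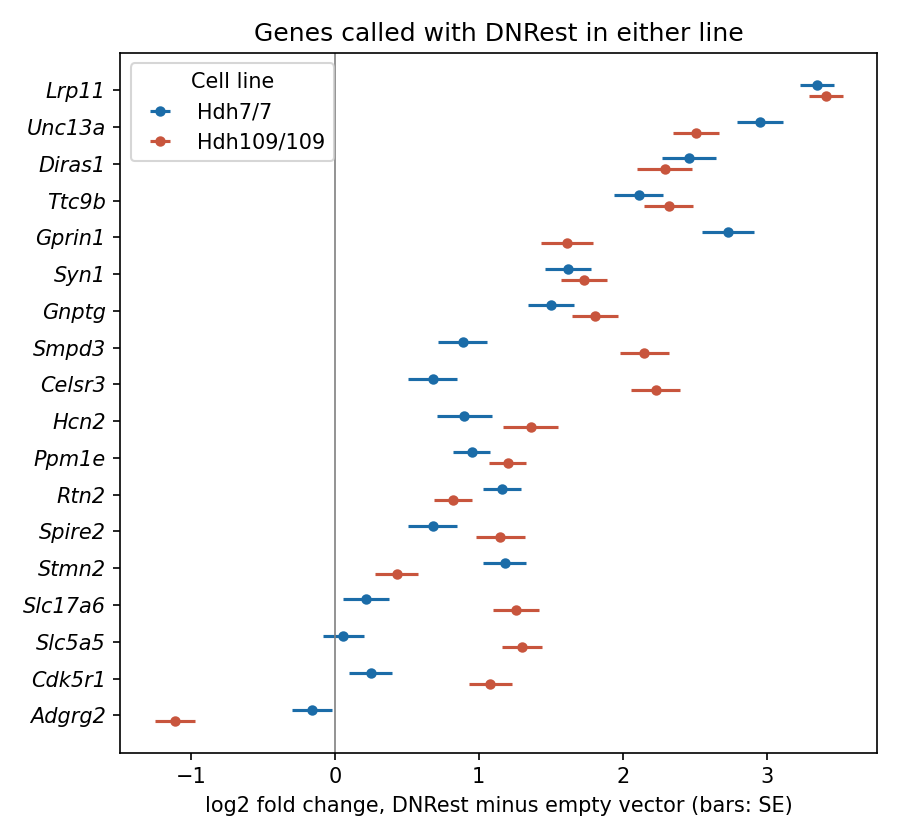
Log2 fold change of DNRest against empty vector (horizontal axis) in Hdh7/7 and Hdh109/109 cells for the 18 genes called in either line. Bars are standard errors from the fit with 2 arrays per group, and Lrp11 stands highest in both lines, at 3.35 and 3.41.

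No probe responded to DNRest with a called difference between the lines (limma, 0 of 15224; 1247 at an unadjusted p under 0.05, smallest adjusted p 0.294). Lrp11, detected in every group, differed by 0.06 (95% interval -0.32 to 0.43). Of the 18 genes called with DNRest in either line or in the average, 8 had a difference when adjusted over these genes alone, but they were chosen by their response, and several were undetected with the empty vector. Among the REST targets, adjusted over the list alone, Celsr3 and Cdk5r1 had a higher response in Hdh109/109 cells and Stmn2 a lower one. Without Hdh7/7 empty vector replicate 1 the count was 825. Median scaling and the series matrix each gave 2.

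The overlap of the 2 questions was also tested, whether genes lower in Hdh109/109 cells rose there with DNRest. Of 1773 genes lower and 15 that rose, 6 were shared, with 3.13 expected (Fisher's exact test, p = 0.103). They were Gnptg, Hcn2, Cdk5r1, Diras1, Syn1 and Gprin1, named as the whole overlap after it was seen. Another 3 that rose were higher in Hdh109/109 cells, against 2.71 expected, and 0 genes were higher between the lines and fell with DNRest. It was 3 without either Hdh7/7 DNRest replicate, without Hdh109/109 empty vector replicate 2 or without Hdh109/109 DNRest replicate 1, 4 without Hdh7/7 untransfected replicate 1 and 20 without Hdh109/109 empty vector replicate 1. Across 8487 genes, which are not independent replicates, the 2 log2 fold changes had r = -0.0477. By the same exact test the overlap was 5 without Hdh7/7 untransfected replicate 2 (p = 0.0383) and 5 without Hdh109/109 untransfected replicate 2 (p = 0.0467).

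Transfection itself was followed by an interferon response in 1 of the lines. Averaged over the lines, 21 of 23 interferon response genes rose with the empty vector, with a median of 1.35 (camera adjusted p = 3.89e-27, and adjusted p = 0.0224 with an estimated correlation). Among the genes with the highest changes were the antiviral genes Rsad2, at least 5.12-fold, and Mx2, at least 2.23-fold, the chemokine genes Cxcl10 and Ccl5, and Gbp3, Apol9a, Apol9b, Ifi47 and Oasl1. Adjusted over the list alone, 22 rose. By line, 22 of 23 rose in Hdh109/109 cells with a median of 2.9, while in Hdh7/7 cells 1 rose and 2 fell with a median of -0.08. With undetected probes at their bound the Hdh7/7 median was 0.5. This value is the offset between the arrays' lowest detected signals and no rise of these genes. Those signals were log2 5.82 and 5.91 without transfection and 5.99 and 6.73 with the vector. The difference between the lines had a median of 3.16 and 21 genes called (camera adjusted p = 9.01e-21, and adjusted p = 0.0448 with an estimated correlation). With undetected probes at their bound the medians were 2.68 in Hdh109/109 cells and 2.67 for the difference, which also carries the Hdh7/7 offset. Rsad2 rose at least 51-fold in Hdh109/109 cells, Mx2 at least 10.4-fold and Cxcl10 32.6-fold. In Hdh7/7 cells Ccl5 was called higher, and Igtp, at least 1.12-fold, and Irf9 were called lower.

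**Figure D3:**
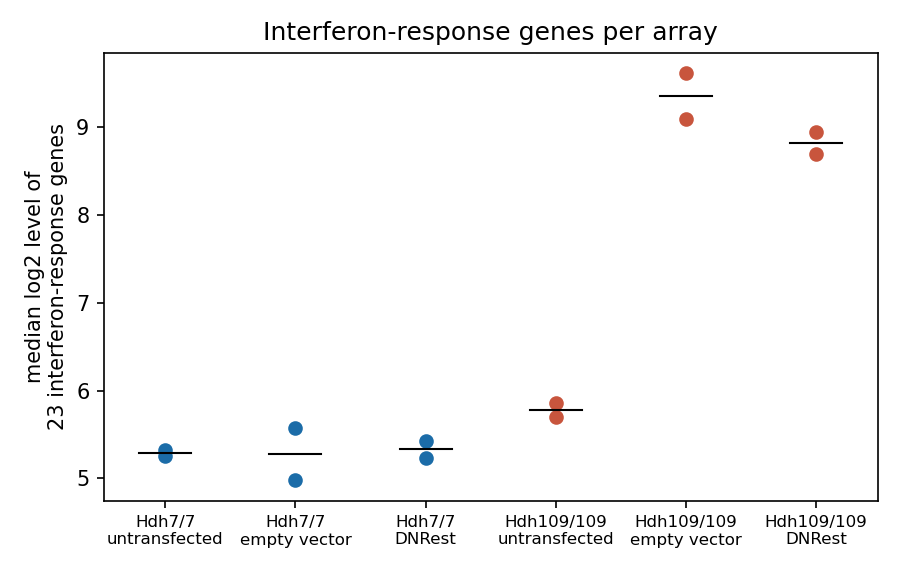
Median log2 level of 23 interferon-response genes (vertical axis) on each of the 12 arrays, by group. Bars are group means, and the 4 transfected Hdh109/109 arrays lie at 8.69 to 9.61, with the other 8 at 4.98 to 5.86.

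Other genes also followed the vector. Averaged over the lines 536 probes rose and 643 fell, and the water channel gene Aqp1 (-1.26 ± 0.1) fell in both lines. The matrix gene Spon2 and the kinase gene Mylk, also called in the average, fell in Hdh7/7 cells (-2.75 ± 0.16 and -2.62 ± 0.17). In Hdh109/109 cells their log2 levels were 10.28 and 6.26 without transfection and 10.25 and 6.19 with the vector (difference between the lines in the limma fit, adjusted p = 0.000147 and 0.000326). The lowest detected signals on the untransfected Hdh109/109 arrays were log2 5.75 and 6.2. Mylk lay near them, so a fall of the size in Hdh7/7 cells could not have been seen. Its difference between the lines is therefore set in part by the floor. In Hdh7/7 cells 940 probes rose and 1447 fell, with lower Trp63, Slc40a1, an iron exporter, and the immediate early genes Fos (-2.35 ± 0.21) and Egr2. Trp63, Slc40a1 and Egr2 were detected on 1 of 2 arrays with the vector. Mesenchymal and matrix genes fell in 11 of 24 in that line, with Col6a1 at -1.69 ± 0.12 and Lox at -1.73 ± 0.22 (camera adjusted p = 0.00341, and adjusted p = 0.516 with an estimated correlation). Cell cycle genes rose in 5 of 21 there, with a median of 0.2 (adjusted p = 0.00563, and adjusted p = 0.159 with an estimated correlation). With median scaling that median was -0.3, beside a shift of -0.45 in all probes. In Hdh109/109 cells 298 probes rose and 146 fell, and the prolactin family genes Prl2c2 and Prl2c3 were at least 3.12-fold lower and 5.15-fold lower, the latter with signal in both groups. The response differed between the lines for 1834 probes, 1086 with a higher and 748 with a lower response in Hdh109/109 cells. The counts for the vector moved with single arrays. The average of 1179 was 361 and 459 without Hdh7/7 untransfected replicate 1 and 2, 527 and 608 without Hdh109/109 untransfected replicate 1 and 2, 783 without either Hdh109/109 DNRest replicate, and 2163 without Hdh7/7 empty vector replicate 1. In Hdh7/7 cells the count of 2387 was 703 and 930 without its untransfected replicate 1 and 2, and 3834 and 1138 without its empty vector replicate 1 and 2. In Hdh109/109 cells the count of 444 was 187 and 194 without its untransfected replicate 1 and 2, 1090 and 172 without its empty vector replicate 1 and 2, and 281 without either Hdh7/7 DNRest replicate. The difference of 1834 was 671 and 1034 without Hdh7/7 untransfected replicate 1 and 2, 3453 and 1205 without Hdh7/7 empty vector replicate 1 and 2, 1122 and 885 without Hdh109/109 untransfected replicate 1 and 2, and 1064 without Hdh109/109 empty vector replicate 2. With median scaling 126 probes rose and 525 fell in the average. With the arrays of the compared groups alone, 1 probe was called in Hdh7/7 cells, 225 in Hdh109/109 cells, 316 in the average and 679 for the difference. The shared spread understates the noise of the Hdh7/7 empty vector group. Standard errors and counts above that use this group therefore tend to be too favourable.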

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

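The tests of the empty vector by line, of other cells in the cultures, of 1 aberrant array and of the amount of vector were chosen after the results were seen. The tests of other splits of the arrays and of the arrays with high background were written down before.

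Interferon response genes responded to the empty vector differently in the lines, with a median log2 difference of 3.16 between Hdh109/109 and Hdh7/7 cells. Without the 2 arrays with high background the median was 3.03, which argues against these arrays as its source. On each of the 4 transfected Hdh109/109 arrays the list's median level lay at least 2.83 log2 above the highest of the other 8 arrays, which argues against 1 aberrant array. Less vector in Hdh7/7 cells stays open: an unnamed probe that is bright on transfected arrays alone was only 0.14 log2 higher in transfected Hdh109/109 cells, but its target is unknown and it may be near saturation. A different innate response of the Hdh109/109 line is a candidate explanation, and with 1 line per genotype the repeat and the line cannot be separated.

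The 2 lines differed at 8785 probes averaged over the transfection states. In a model with line and transfection as separate terms the count was 7759. Of 100 splits of the 12 arrays, drawn from 462, 1 gave as many, the real one, and the highest other gave 526. This argues against a chance arrangement of the arrays. Most other splits part arrays of 1 group, which may not be separate cultures, so chance between cultures is not excluded. Without the 2 arrays with high background 8632 probes were called. A minor share of other cells in the Hdh109/109 cultures would dilute the neural progenitor markers by at most 2-fold, but 5 called markers fell by more, Nes 3.02-fold, Hes1 4.89-fold and Id1, detected on 4 of 6 Hdh109/109 arrays, 7.78-fold in untransfected cells where it was detected on all arrays, with Sox2 at least 23.4-fold and Pax6 at least 16.9-fold, which argues against it as their whole cause; of the other called markers Id3 fell 1.41-fold, Notch1 rose by 0.28 log2 and Prom1, undetected in Hdh109/109 cells, gives no bound. Genotype, clonal differences and passage history remain open and were not tested.

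DNRest changed 21 probes averaged over the lines. In a model with line and construct as separate terms 14 probes were called. Of 34 splits of the 8 transfected arrays 1 gave as many, the real one, and the highest other gave 0. These splits are few, move arrays across the 2 lines and part arrays of 1 group, which may not be separate cultures. They therefore do not exclude chance. Of the 21 probes, 18 were also called without the 2 arrays with high background. For the empty vector against no transfection the same kind of model called 1 probe, and 2 of 34 splits gave as many, the highest other 31. This model counts the difference between the lines in the vector response as noise, while the fit with group means called 1179. Chance is therefore not excluded for that averaged count, and these splits could not decide it. The split with 31 calls set Hdh7/7 untransfected and Hdh109/109 empty vector arrays against the rest, which points to the difference between the lines in the vector response. In both families 1 of 35 splits could not be fitted.

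The response to the empty vector differed between the lines for 1834 probes by a test of the difference itself, and by the same kind of test for mesenchymal and matrix genes, with a median difference of 0.57 (camera adjusted p = 0.00204, and adjusted p = 0.439 with an estimated correlation). For the DNRest response camera called a difference for interferon response genes, with a median of -0.37, and for endoplasmic reticulum stress genes, with a median of -0.16, but 0 of 23 and 0 of 18 genes were called, and both lists had adjusted p = 0.852 with an estimated correlation. The interferon call was lost without Hdh109/109 empty vector replicate 2 (adjusted p = 0.135) and without Hdh109/109 DNRest replicate 1 (0.0728), and its median was -0.61 without Hdh109/109 DNRest replicate 2 and -0.57 without Hdh109/109 empty vector replicate 1. The stress call, with an adjusted p of 0.0488, was lost in 11 of 12 fits that left out 1 array, all but that without Hdh7/7 DNRest replicate 1, with adjusted p up to 0.232. Its median was -0.26 and -0.1 without Hdh7/7 empty vector replicate 1 and 2. No explanation was tested for them.

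Single arrays lay far from the others of their line in 5 of 46 sets of 6 arrays tested, by a test with a 5% level. That level assumes arrays that differ by noise alone, but each set spans the transfection states and the sets share arrays. The share expected by chance is therefore not known. Hdh7/7 empty vector replicate 2 had a median signal of 161.1 and 10295 probes detected, and Hdh109/109 untransfected replicate 2 had a median signal of 156.1. On Hdh109/109 empty vector replicate 2 the log2 level of Dlk1 was 12.04 and that of Atp6v0e2 was 4.9. The value of Atp6v0e2 lies under the lowest detected signal of that array, log2 5.65, and is no measured level. The cause was not tested.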

How the results depend on the processing

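The alternatives without the pair of arrays with high background, without these and Hdh109/109 empty vector replicate 2, and for the vector in each line were chosen after the data were seen.

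Of the named gene results, 325 of 334 kept direction and call without background correction, 277 with median scaling, 306 without a detection filter, 327 with a trended and robust spread, 228 with the compared groups alone, 286 without the pair with high background and 280 without 3 arrays. All 143 that could be fitted kept both with probes detected on all 12 arrays. With at least 2-fold, 240 of 334 kept their call.

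With median scaling the median of all probes moved to 0.26 for the averaged genotype, 0.11 and -0.31 for DNRest in Hdh7/7 and Hdh109/109 cells, -0.43 for their difference, and -0.16, -0.45, 0.14 and 0.63 for the vector averaged, in Hdh7/7 cells, in Hdh109/109 cells and for their difference. The counts were then 3242 for genotype without transfection, 117 for DNRest in Hdh109/109 cells, 2 for the DNRest difference and 651 for the averaged vector. REST targets between untransfected lines had a median of -0.07 with the test's direction reversed, and endoplasmic reticulum stress genes 0.74 in the averaged genotype (adjusted p = 0.0568). Foxp1 reversed to 0.09 for the vector difference and Rrm2 to -0.01 for the vector in Hdh7/7 cells. The cause was not tested.

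Without background correction 33 probes were called for DNRest in Hdh109/109 cells and 922 for the vector there. Without a detection filter the averaged vector gave 779, and REST targets had a median of 0 with DNRest in Hdh7/7 cells (adjusted p = 0.76). A trended and robust spread gave 857 for the vector in Hdh109/109 cells. The cause was not tested.

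With probes detected on all 12 arrays, which removes every gene undetected in a group, Gjb2 and Sox2 among them, DNRest gave 4 calls in Hdh7/7 cells, 11 in Hdh109/109 cells and 9 averaged, and the vector gave 698 in Hdh109/109 cells. Medians that were no longer called were -0.35 for progenitor markers, 0.06 and 0.39 for REST targets with DNRest in Hdh7/7 and Hdh109/109 cells, 0.44 for mesenchymal genes and 0.27 for non-coding and imprinted RNAs.

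With the compared groups alone, where the spread comes from those arrays only, DNRest gave 0 calls in Hdh7/7 cells (limma, with 643 at an unadjusted p under 0.05) and 13 in Hdh109/109 cells. The vector gave 316 averaged, 1 in Hdh7/7 cells, 225 in Hdh109/109 cells and 679 for the difference. Genotype without transfection, also 2 arrays against 2, gave 5388. The replicate SD was 0.343 log2 in the Hdh7/7 empty vector group and 0.176 to 0.249 in the others, so the shared spread understates the noise of that group. With at least 2-fold the counts were 2148 and 1896 for genotype without transfection and averaged, and 99, 634, 221 and 1136 for the vector averaged, in Hdh7/7 cells, in Hdh109/109 cells and for the difference, fewer by construction.

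With an estimated correlation the medians of -2.18 for progenitor markers without transfection, and of 0.76 for mesenchymal genes, 0.5 for endoplasmic reticulum stress, -0.76 for p53 targets and 1.42 for non-coding and imprinted RNAs in the averaged genotype, were no longer called. The series matrix gave 9 for DNRest in Hdh109/109 cells, 11 averaged and 2 for the difference, and 588, 190 and 1027 for the vector averaged, in Hdh109/109 cells and for the difference. The cause was not tested.

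Without the pair with high background the vector gave 533 averaged, 1093 in Hdh7/7 cells and 744 for the difference. Without 3 arrays it gave 568 averaged, 213 in Hdh109/109 cells and 714 for the difference. In single states, with fewer arrays, the genotype count was 5422 without transfection and 5596 with DNRest, Hspd1 reversed to 0.16 without transfection and Flt1 to 0.08 with DNRest.

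Within a transfection state the source name varied only among the empty vector arrays, where it separated replicate 2 from replicate 1 in each line. Used as genotype, it therefore compared replicates and not the lines, and its values are no alternative genotype effect. With it 0 probes were called (limma, with 325 at an unadjusted p under 0.05), and 31 of 71 genes named for the averaged genotype reversed. They were Gask1b (-0.3), Dlk1 (-0.16), Atp6v0e2 (0.2), Sall3 (0.04), Bmper (0.04), Bex1 (0.15), Dnm1 (-0.22), Ctdsp2 (-0.04), Pde1b (0.05), Dlx2 (-0.46), Penk (-0.32), Slc1a3 (-0.53), Apoe (-0.11), Glul (-0.41), Col3a1 (-0.22), Dcn (-0.25), Hsd17b7 (0), Cxcl10 (-0.38), Ccl5 (-0.49), Psmb8 (-0.19), E2f1 (0.09), Atf3 (-0.1), Ddit3 (-0.41), Hspb8 (0.01), Hspd1 (0.45), Mdm2 (0.34), Pmaip1 (0.28), Ppargc1a (0.26), Uqcrc1 (-0.01), Pdk4 (0.11) and Igf2 (-0.41).

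Leaving out each array in turn, the lone array of its group being assumed to vary like the other groups, gave 3746 to 6010 for genotype without transfection and 7870 to 9055 averaged. DNRest gave 7 to 1129 in Hdh7/7 cells, 11 to 268 in Hdh109/109 cells, 15 to 205 averaged and 0 to 825 for the difference. The vector gave 361 to 2163 averaged, 703 to 3834 in Hdh7/7 cells, 172 to 1090 in Hdh109/109 cells and 671 to 3453 for the difference, and the reversal overlap was 3 to 20. REST targets ranged from -0.05 to 0.09 between untransfected lines, reversed without Hdh7/7 untransfected replicate 1, and from 0.18 to 0.25 and 0.44 to 0.52 with DNRest in Hdh7/7 and Hdh109/109 cells. Progenitor markers ranged from -2.2 to -2.16 between untransfected lines, and interferon genes from 1.26 to 1.44 for the averaged vector and 3.09 to 3.3 for its difference between the lines. In the averaged genotype mesenchymal genes ranged from 0.74 to 0.79, endoplasmic reticulum stress from 0.45 to 0.56, p53 targets from -0.83 to -0.72 and non-coding and imprinted RNAs from 1.32 to 1.52.

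The replicate number as a block gave 5040 and 8508 for genotype, 15, 18, 17 and 0 for DNRest in Hdh7/7 cells, in Hdh109/109 cells, averaged and as a difference (limma; 1125 for the difference at an unadjusted p under 0.05), and 862, 1996, 330 and 1418 for the vector averaged, in Hdh7/7 cells, in Hdh109/109 cells and as a difference. Over 15 pairs of groups the replicate numbers correlated at r = -0.445 to 0.359, so they do not pair the arrays. Slide as a block was not run. Signal over background limits genes undetected in a group, whose changes are lower bounds.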

Other observations

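The probe below was chosen after its values were seen, and no test of it was planned.

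A probe without a gene name in the annotation, ILMN_2476406, had a log2 level of 14.97 or more on the 8 transfected arrays and of 4.74 or less on the 4 untransfected ones. The empty vector raised it at least 779-fold in Hdh7/7 cells and at least 692-fold in Hdh109/109 cells. Its target is not given in the sources used here.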
